A study of Homo sapiens with 23 samples.

How the data were processed

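The deposited values were taken as log2 signals of RNA on Affymetrix arrays with 54675 probe sets, computed by the authors. Per the submitters' processing notes, RMA and Partek were used, with no version named. RMA summarizes the probes of a probe set on a log scale after background adjustment and quantile normalization. The labels give total RNA, extraction with Trizol and biotin labelling by in vitro transcription from the 3′ end. The dose and duration of tamoxifen, the growth of the cells, the way Y537S was introduced and a genome build are not given in the sources used here. The base of the logarithm was not stated either and was taken as 2. The hybridization controls cre (100 pM) and bioB (1.5 pM) differed by 5.79 ± 0.15 (SD over 23 arrays), against 6.06 for log2 and 4.2 for natural logarithms.

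Groups were read from the line, genotype and treatment in the labels, and columns were matched to samples by the sample identifier at the head of each column. The deposited table held no column of other samples. The values ran from −0.5252 to 12.49. Of the probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none listed. Only those with 1 symbol were used, and for each of the 19775 genes the probe set with the highest mean over all arrays was tested. More than 1 probe set was present for 10523 genes, and 8544 genes had a mean of at least 3. Symbols of 41043 probe sets were looked up by Entrez number in a RefSeq gene table, which changed none. No filter on dim probe sets was applied.

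One linear model with a mean for each of the 8 groups was fitted to all 23 arrays with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with a prior of 5.7 and a residual of 15 degrees of freedom. Contrasts were the tamoxifen effect in each genotype, the genotype effect with and without tamoxifen and the interaction in each line, and the differences of these effects between lines (MCF7C minus ZR75). Benjamini-Hochberg adjustment was made within each comparison, and genes with an adjusted p under 0.05 were called. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 19 lists of a comparison, and again with the correlation estimated from the data and with the rotation test fry. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Members of lists were counted both over all genes and with p adjusted over the list alone.

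The model, the gene lists, the alternatives and the genes to be named were set before the data were examined. The lists were estrogen-induced, estrogen-repressed, IGF and insulin signalling, DNA replication and G1/S, mitotic, interferon-stimulated, cholesterol synthesis, unfolded protein and amino acid stress, luminal epithelial, basal epithelial, mesenchymal and matrix, blood and endothelial, hypoxia and glycolysis, p53 target, apoptosis, receptor tyrosine kinase, coregulator, respiratory chain, and lysosome and autophagy genes. The named genes were ESR1, PGR, TFF1, GREB1, IGF1R, IRS1 and IGFBP4 in every comparison. Added to these were the 8 largest rises and 8 largest falls of each genotype effect without tamoxifen and the 6 and 6 of each tamoxifen effect, among called genes whose groups did not overlap. The 8 highest and 8 lowest called in both lines by the smaller change, and up to 4 called members with the smallest p of each list past its test, were named too. Where an interaction called no gene, the 4 with the smallest p were named. Open reading frames were counted but not named, except where the lines differed.

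Alternatives were each line fitted on its own, trend and robust moderation, array weights, leaving out the lowest 33.3% of genes by mean, the mean of a gene's probe sets and quantile normalization again within each line. Others were centring on array medians, the replicate number as a block, each array left out in turn, and a minimum change of 1 log2 unit. A further one, without 2 arrays whose control probe sets stand apart, was chosen after seeing the data. Overlaps were compared with the product of both lists over the genes tested. The response score was the mean change, signed by direction, of genes called in both genotypes of the other line. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

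The fit was tested on simulated data with the group sizes and spread of these arrays, in which 200 of 19775 genes were changed by 0.5, 1 or 2 log2 units. For genotype effects without tamoxifen 52.2%, 97% and 100% were recovered in MCF7C cells and 41.8%, 91% and 100% in ZR75 cells, with 12 and 15 false calls. With tamoxifen 61.2%, 95.5% and 98.5% were recovered in MCF7C cells and 70.1%, 97% and 100% in ZR75 cells, with 12 and 8 false calls. For the tamoxifen effect in WT the shares were 53.7%, 97% and 100% in MCF7C cells (7 false calls) and 32.8%, 97% and 100% in ZR75 cells (11 false calls). For the interaction they were 17.9%, 88.1% and 98.5% in MCF7C cells (3 false calls) and 29.9%, 71.6% and 100% in ZR75 cells (6 false calls). Where no gene was changed, 0 genes were called.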

Results

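Gene expression was profiled in MCF7C and ZR75 cells, lines of human breast cancer cells of the estrogen receptor-positive type. Each line was studied with wild-type (WT) ESR1, the gene of estrogen receptor alpha, and with the Y537S mutation, a substitution in the ligand-binding domain known to keep the receptor active without estrogen. Cells of each genotype were sampled without (Control) and with tamoxifen, a drug that binds the receptor and blocks its activity in breast cells. The 23 arrays fell into 8 groups, with 3 arrays in each group except ZR75 WT Control, which had 2. The title given to the series asks whether ESR1 mutations alter the response to tamoxifen through insulin-like growth factor (IGF) signalling. Accordingly, the tamoxifen effect was measured in each genotype, the genotype effect was measured with and without tamoxifen, and the difference between the tamoxifen effects, called the interaction here, was tested in each line.

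Values were log2 signals of 54675 probe sets, from which 19775 genes were tested. Arrays of the same group correlated across genes with r = 0.9951 to 0.9969, and arrays of different lines with r = 0.9366 to 0.9459. Genes are not independent replicates, so these values describe similarity only. No pair of arrays held identical values, as the smallest SD of the differences within a pair was 0.197. The median signal of an array lay between 0.972 and 1.09, and values under about 2 were near the floor of the scale, where differences are understated. The number of arrays limits the precision, and the median SE was 0.12 to 0.13 for tamoxifen and genotype effects within a line. It was 0.17 in MCF7C and 0.18 in ZR75 cells for the interaction, and 0.17 to 0.25 for differences between lines. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. Differences are given below as log2 values ± SE from limma, with levels as mean ± SD over the arrays of a group.

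ESR1 itself was highly expressed in every group and rose with tamoxifen in MCF7C cells. Its level was 8.49 ± 0.06 in MCF7C WT Control cells and 9.32 ± 0.12 with tamoxifen, a difference of +0.83 ± 0.08, adjusted p = 4.7e-08. In MCF7C Y537S cells it went from 8.69 ± 0.09 to 9.33 ± 0.02, a difference of +0.65 ± 0.08, adjusted p = 1.8e-06. ZR75 cells had 7.52 ± 0.05 and 7.51 ± 0.04 in WT cells and 7.68 ± 0.04 and 7.79 ± 0.06 in Y537S cells, and no difference in that line passed the threshold in the main model. These values come from the brightest of the 9 ESR1 probe sets (mean 8.32 over all arrays, against 0.60 to 3.39 for the others). With the mean of the 9 in its place, which gives the dim probe sets equal weight, the rise in MCF7C WT cells was 0.18 (adjusted p = 0.071). By that mean ESR1 was lower in ZR75 Y537S than in WT cells under tamoxifen, at −0.35 ± 0.07 (adjusted p = 0.016) against +0.28 ± 0.08, adjusted p = 0.12 with the brightest probe set. Trend and robust moderation called the brightest one higher (adjusted p = 0.009), so these 2 alternatives called opposite directions. The probe sets measure the amount of RNA and cannot show the point mutation.

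The genes fixed for every comparison before the data were examined included known estrogen targets, which fell under tamoxifen in both genotypes. PGR, the progesterone receptor gene and a standard estrogen target, fell by 13.1-fold in MCF7C WT and 15.2-fold in MCF7C Y537S cells (log2 −3.71 ± 0.11 and −3.92 ± 0.11) and by 3.69-fold and 3.41-fold in ZR75 cells (−1.88 ± 0.12 and −1.77 ± 0.11). With tamoxifen PGR was near the floor in MCF7C Y537S cells (mean 1.95), so that its fall there is a lower bound. GREB1, a cofactor and target of the receptor, fell in MCF7C WT and Y537S cells (−1.97 ± 0.20 and −1.46 ± 0.20) and in ZR75 WT and Y537S cells (−3.45 ± 0.22 and −2.90 ± 0.20). TFF1, a secreted trefoil peptide, fell as well, with −0.76 and −0.96 in MCF7C and −1.38 and −1.15 in ZR75 cells. Of the IGF pathway genes, IRS1, the adaptor of the IGF and insulin receptors, fell in all 4 tamoxifen comparisons (−0.88 ± 0.10 and −0.85 ± 0.10 in MCF7C, −1.14 ± 0.11 and −1.09 ± 0.10 in ZR75). IGF1R, the IGF receptor gene, fell in ZR75 WT cells (−0.88 ± 0.13, adjusted p = 6.1e-05), and in ZR75 Y537S cells (−0.52 ± 0.11, adjusted p = 0.004). It also fell in MCF7C WT cells (−0.45 ± 0.11, adjusted p = 0.0059), a call not past the threshold without MCF7C WT Tamoxifen 3 (−0.32, adjusted p = 0.056). In MCF7C Y537S cells IGF1R was at −0.31 ± 0.11, adjusted p = 0.06, and past the threshold without MCF7C Y537S Control 3 (−0.40, adjusted p = 0.031). IGFBP4, which binds IGFs outside the cell, fell in MCF7C cells (−0.67 ± 0.12 and −0.54 ± 0.12), with ZR75 values of −0.30 and +0.13 not past the threshold. The plot of single genes by group shows each array for all of these genes but IGFBP4.

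**Figure D1:**
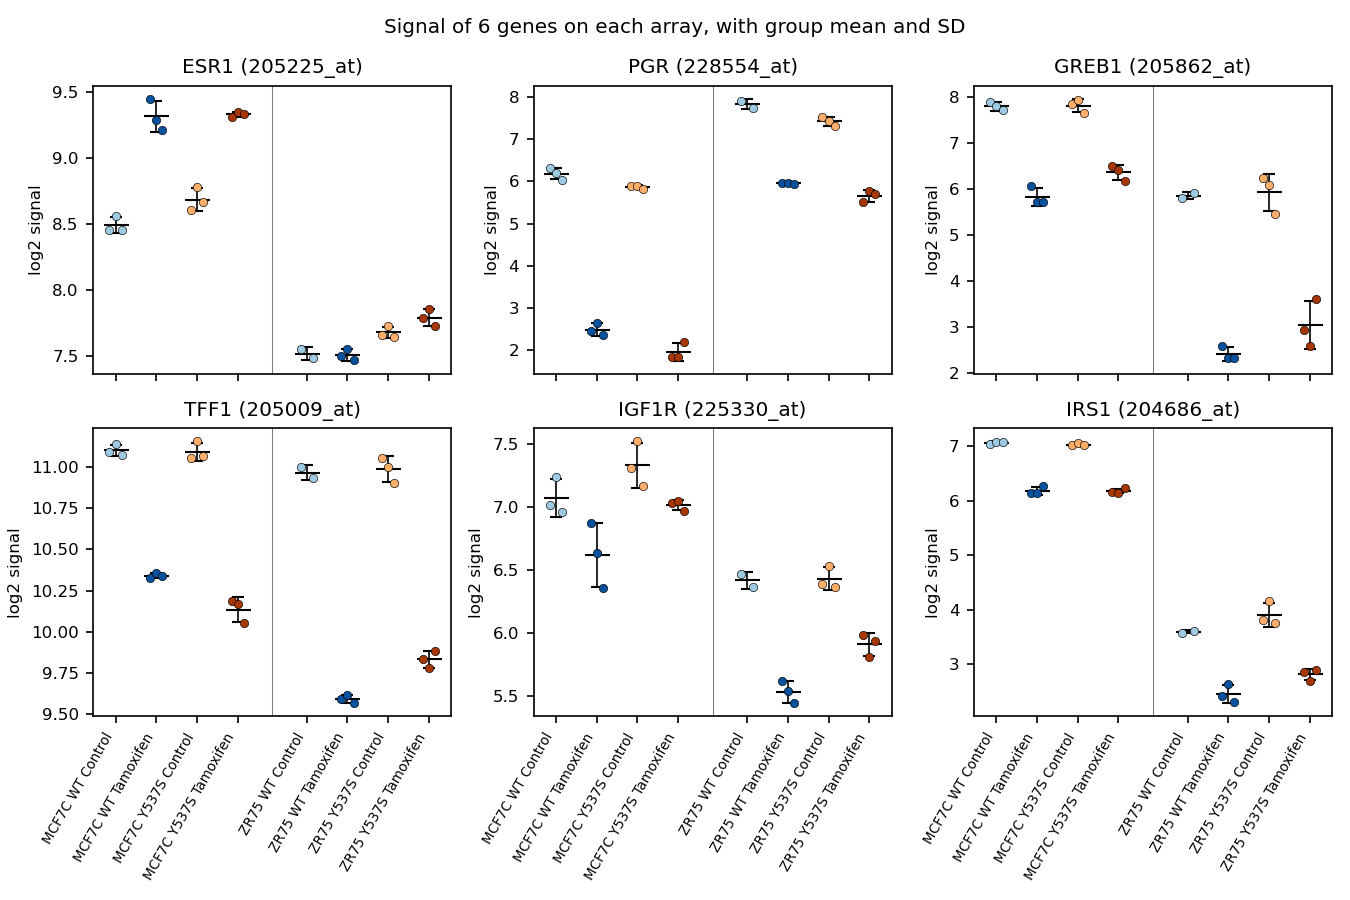
Log2 signal (vertical axis) of ESR1, PGR, GREB1, TFF1, IGF1R and IRS1 in the 8 groups (horizontal axis), with 1 point per array and a bar at the group mean. PGR, GREB1 and TFF1 lie lower with tamoxifen in both genotypes of both lines, and ESR1 lies higher with tamoxifen in both genotypes of MCF7C cells.

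What tamoxifen did in MCF7C cells with the wild-type receptor was the first question. The largest rises were those of CCN2, a matricellular growth factor (+3.56 ± 0.19, adjusted p = 1.6e-11), CSTA, a cysteine protease inhibitor (+3.47 ± 0.20, adjusted p = 6.5e-11), and the early response gene IER3 (+2.91 ± 0.07, adjusted p = 1.9e-17). SOCS3, a feedback inhibitor of cytokine signalling, rose as well (+2.56 ± 0.11, adjusted p = 7.9e-13). PPFIBP2 was at +2.70 ± 0.11. The largest falls after PGR were those of the scaffold gene PDZK1 (−3.51 ± 0.21, adjusted p = 1.1e-10), the protease gene PRSS23 (−3.20 ± 0.15, adjusted p = 4.1e-12) and ELOVL2, an elongase of polyunsaturated fatty acids (−3.04 ± 0.13, adjusted p = 3.8e-13). THBS1, which encodes thrombospondin 1, fell by a similar amount (−2.88 ± 0.12, adjusted p = 6.5e-13), and PPM1K was at −2.78 ± 0.15. The lower level was under 2 for CCN2, PDZK1 and ELOVL2, so that these changes are lower bounds. Altogether 4078 genes passed the threshold, 1954 higher and 2124 lower, with a median size of 0.483.

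Of the 47 measured estrogen-induced genes, 26 fell and 11 rose in these cells (26 and 12 when adjusted over the list alone), PDZK1, PRSS23 and ELOVL2 among the falls. Of the 20 measured estrogen-repressed genes, 14 rose and none fell (17 and 1 when adjusted over the list alone), among them TP53INP1, a stress protein gene (+1.97 ± 0.10), YPEL3 (+1.83 ± 0.12) and the pro-apoptotic gene BIK (+1.15 ± 0.10). DNA replication and G1/S genes fell as a group, 37 of 39, both over all genes and adjusted over the list alone, with MCM10 at −1.05 ± 0.13, GINS4 at −0.96 ± 0.11 and FEN1 at −0.68 ± 0.08. Mitotic genes fell in 26 of 40 cases (29 adjusted over the list alone), with CDC20 at −0.61 ± 0.08 and BUB1B at −0.40 ± 0.07. Luminal epithelial genes rose, 18 of 23 with 1 lower (20 and 1 adjusted over the list alone), including CD24 (+1.08 ± 0.07) and the epithelial transcription factor genes SPDEF (+1.15 ± 0.10) and ELF3 (+1.07 ± 0.10). Of the p53 target genes, 7 of 23 rose and none fell by either adjustment, among them CDKN1A, the cell cycle inhibitor p21 (+1.28 ± 0.10), GDF15 (+1.43 ± 0.09) and PLK2 (+1.01 ± 0.10). In camera, adjusted p for these 6 lists was 0.0057, 0.00064, 0.0051, 0.0059, 0.00041 and 0.0051 with an estimated correlation, in the order given.

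A further 5 lists passed with the preset correlation in MCF7C WT cells and did not hold with an estimated one. IGF and insulin signalling genes had 10 of 39 higher and 4 lower (15 and 5 adjusted over the list alone), with IGFBP5 at +1.47 ± 0.11, PIK3R3 at +0.67 ± 0.08, GRB14 at −1.21 ± 0.17 (near the floor) and IRS1 lower as given above; adjusted p = 0.19 with an estimated correlation. Hypoxia and glycolysis genes had 9 of 26 lower and 3 higher (11 and 3 adjusted over the list alone), with lactate dehydrogenase gene LDHA at −0.75 ± 0.09 and BNIP3 at −0.63 ± 0.10 against the glucose transporter gene SLC2A1 at +0.97 ± 0.08; adjusted p = 0.25 with an estimated correlation. Lysosome and autophagy genes had 12 of 26 higher and 4 lower (13 and 4 adjusted over the list alone), with WIPI1 at +0.92 ± 0.10, ULK1 at +0.85 ± 0.11 and CTSD, a cathepsin gene that estrogen induces, at −0.70 ± 0.11; adjusted p = 0.083 with an estimated correlation. Nuclear receptor coregulators had 9 of 23 lower and 3 higher (9 and 4 adjusted over the list alone), with KDM1A at −0.59 ± 0.09 and NRIP1 at −0.87 ± 0.08; adjusted p = 0.083 with an estimated correlation. Interferon-stimulated genes had 8 of 43 higher and 2 lower (10 and 3 adjusted over the list alone), with PARP9 at +1.43 ± 0.21 and HERC6 at −0.72 ± 0.20; adjusted p = 0.39 with an estimated correlation.

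The same question was then asked of MCF7C cells with the mutant receptor. CSTA (+2.94 ± 0.20, adjusted p = 9.9e-10), CCN2 (+2.92 ± 0.19, adjusted p = 4.2e-10), IER3 (+2.70 ± 0.07, adjusted p = 8.2e-17) and SOCS3 (+2.58 ± 0.11, adjusted p = 9e-13) led the rises, and TM4SF1, a membrane protein gene, was at +2.29 ± 0.12. PGR led the falls, followed by HMGCLL1, an enzyme of ketone body synthesis (down at least 7.99-fold, adjusted p = 8.6e-11; mean 0.79 against 3.79, near the floor), PRSS23 (−2.83 ± 0.15), ELOVL2 (−2.63 ± 0.13), PPM1K (−2.59 ± 0.15) and PDZK1 (−2.55 ± 0.21). The changes of CCN2, PRSS23, ELOVL2 and PDZK1, with a level under 2 in 1 group, are lower bounds too. In total 3585 genes passed the threshold, 1737 higher and 1848 lower, with a median size of 0.473. Of these genes, 1305 were higher and 1401 lower in MCF7C WT cells too, against 172 and 198 for independent lists, and 3 went opposite ways. Those 3 genes, RAB3A, TAL1 and TMEM169, were singled out after their values were seen (+0.34, −0.43 and −0.53 in WT, −0.32, +0.36 and +0.53 in Y537S cells), TAL1 and TMEM169 near the floor. Across genes, which are not independent replicates, the differences in the genotypes correlated with r = 0.811.

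Estrogen-induced genes in MCF7C Y537S cells had 23 of 47 lower and 12 higher (28 and 13 adjusted over the list alone). Estrogen-repressed genes there had 12 of 20 higher and none lower (16 and 1 adjusted over the list alone), with TP53INP1 at +1.63 ± 0.10 and YPEL3 at +1.61 ± 0.12. DNA replication genes fell in 38 of 39 cases by either adjustment, among them the helicase gene MCM6 (−0.91 ± 0.09) and the origin licensing gene CDC6 (−1.24 ± 0.12). Luminal genes rose in 16 of 23 cases with 1 lower (18 and 1 adjusted over the list alone), with CD24 at +1.17 ± 0.07, CLDN4 at +0.95 ± 0.10 and AGR2 at +0.79 ± 0.09. The p53 target genes had 7 of 23 higher and 3 lower by either adjustment, with GDF15 at +1.28 ± 0.09 and CDKN1A at +1.03 ± 0.10. Apoptosis regulators had 6 of 22 higher and 1 lower (8 and 2 adjusted over the list alone), the rises including both the pro-apoptotic BIK (+1.22 ± 0.10) and BAD (+0.52 ± 0.11) and the anti-apoptotic BCL2L1 (+0.70 ± 0.10, but adjusted p = 0.053 with the mean of its probe sets). Lysosome genes had 12 of 26 higher and 3 lower (14 and 4 adjusted over the list alone) and coregulators 9 of 23 lower and 4 higher (10 and 4 adjusted over the list alone), with PELP1 at −0.72 ± 0.12. With an estimated correlation, adjusted p for these 8 lists was 0.0066, 0.0012, 0.0013, 0.0007, 0.0084, 0.023, 0.044 and 0.049 in the order given.

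Mitotic genes in MCF7C Y537S cells had 12 of 40 lower and none higher (16 adjusted over the list alone), with CDC20 at −0.58 ± 0.08 and BUB1B at −0.33 ± 0.07; camera gave adjusted p = 1.6e-05, and adjusted p = 0.063 with an estimated correlation. Hypoxia and glycolysis genes had 13 of 26 lower and 3 higher (14 and 3 adjusted over the list alone), with PDK1 at −1.71 ± 0.16 and SLC2A1 at +0.99 ± 0.08; adjusted p = 0.16 with an estimated correlation. Cholesterol synthesis genes had 6 of 22 lower and 2 higher (7 and 2 adjusted over the list alone), with TMEM97 at −0.72 ± 0.08 and STARD4 at −0.64 ± 0.12; adjusted p = 0.12 with an estimated correlation. The mesenchymal and matrix list had 3 of 28 higher and none lower (2 higher adjusted over the list alone), the matricellular genes CCN2 and CCN1 (+1.10 ± 0.10) and SPARC (+0.44 ± 0.14, near the floor); adjusted p = 0.13 with an estimated correlation. SPARC was not past the threshold without MCF7C Y537S Tamoxifen 2 (adjusted p = 0.15), Control 2 (0.11), Control 3 (0.097) or Tamoxifen 1 (0.063). IGF and insulin signalling genes did not pass (adjusted p = 0.068), with 7 of 39 higher and 3 lower (7 and 4 adjusted over the list alone), while fry, which does not compare them with other genes, gave adjusted p = 0.0036.

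The effect of tamoxifen in ZR75 cells with the wild-type receptor was largest for genes that fell. NPY1R, a neuropeptide Y receptor gene, fell from 7.89 to 3.89 (−4.00 ± 0.12, adjusted p = 1.7e-15), and the zinc finger gene EGR3 fell from 4.10 to 0.62, near the floor (−3.48 ± 0.14, adjusted p = 6.5e-13). GREB1 fell as given above, and TCN1, which encodes a vitamin B12-binding protein, fell as well (−2.95 ± 0.17, adjusted p = 1.9e-10), with CYP2B7P at −2.96 ± 0.20 and PPM1K at −2.28 ± 0.17. The largest rises were those of the long non-coding RNA gene DRAIC (+2.23 ± 0.22, adjusted p = 3.6e-07), the phospholipid flippase gene ATP8A1 (+2.12 ± 0.13, adjusted p = 8.3e-10), the matrix gene NPNT (+1.92 ± 0.09, adjusted p = 1.8e-11) and the atypical chemokine receptor gene ACKR3 (+1.76 ± 0.15). Levels under 2 in 1 group make the values of DRAIC, ACKR3, CYP2B7P and EGR3 lower bounds. The 3′ minus 5′ signal of actin, a sign of RNA quality, was 2.09 in ZR75 WT Control 1 and 3.10 in ZR75 WT Control 2. In the ZR75 arrays of other groups it was 2.01 to 2.48. The threshold was passed by 1753 genes, 771 higher and 982 lower, with a median size of 0.528. Leaving out either control array lowered that count, to 1049 without ZR75 WT Control 1 and to 940 without ZR75 WT Control 2, each of which leaves a single array that is taken to vary like the other groups.

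All 40 mitotic genes fell in ZR75 WT cells, also when adjusted over the list alone, with a median of −0.974. The spindle checkpoint genes BUB1 (−1.17 ± 0.08) and BUB1B (−1.06 ± 0.08) and the anaphase activator gene CDC20 (−1.15 ± 0.09) were among them, with BUB1 at −0.26 (adjusted p = 0.06) by the mean of its probe sets. DNA replication genes fell in 31 of 39 cases (36 adjusted over the list alone), with the nucleotide synthesis genes RRM2 at −0.97 ± 0.08 and TYMS at −0.76 ± 0.08. Estrogen-induced genes had 31 of 47 lower and 1, CCND1, higher (32 and 1 adjusted over the list alone). Of the estrogen-repressed genes 12 of 20 rose and none fell (14 adjusted over the list alone), with TP53INP1 at +1.36 ± 0.12, BIK at +1.12 ± 0.11 and BCAS1 at +1.06 ± 0.12. Cholesterol synthesis genes had 11 of 22 lower and none higher (13 and 1 adjusted over the list alone), with ACAT2 at −0.59 ± 0.10 and EBP at −0.65 ± 0.11. With an estimated correlation, adjusted p for these 5 lists was 1.3e-06, 0.00069, 2.3e-06, 0.0006 and 0.00086. Unfolded protein and amino acid stress genes had 10 of 31 lower and 1, DDIT4, higher (13 and 1 adjusted over the list alone), with the cystine transporter gene SLC7A11 at −1.08 ± 0.14; adjusted p = 0.065 with an estimated correlation. IGF and insulin signalling genes went both ways, 4 of 39 higher and 4 lower (7 and 7 adjusted over the list alone; camera adjusted p = 0.8). The higher members were IGFBP5, GAB1, PIK3R3 and FOXO1 and the lower ones IGF1R, IRS1, GRB14 and EIF4EBP1. The p53 target list, with a median of −0.0144 but a mean of +0.137 and a test that pointed up, did not pass (adjusted p = 0.068), though it did with fry (adjusted p = 2.9e-06).

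ZR75 cells with the mutant receptor answered the same question with many of the same genes. NPY1R (−3.36 ± 0.10, adjusted p = 6.2e-15) and EGR3 (−3.32 ± 0.13, adjusted p = 1.8e-13) fell most, followed by GREB1, TCN1 (−2.88 ± 0.15), CYP2B7P (−2.37 ± 0.18) and PPM1K (−2.17 ± 0.15). LDLRAD4, an inhibitor of transforming growth factor beta signalling (+2.02 ± 0.16), the cell surface gene CEACAM6 (+1.89 ± 0.18), DRAIC (+1.86 ± 0.19) and NPNT (+1.82 ± 0.08, adjusted p = 5.4e-12) rose most. EGR3, CYP2B7P and DRAIC had a level under 2 in 1 group, so that their changes are lower bounds. In all 2012 genes passed, 934 higher and 1078 lower, with a median size of 0.469. Of these, 466 were higher and 715 lower in ZR75 WT cells as well, against 36.4 and 53.5 for independent lists, and none went the other way. The correlation of the differences across genes, which are not independent replicates, was r = 0.682.

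Again all 40 mitotic genes fell in ZR75 Y537S cells by either adjustment, with a median of −0.877, among them BUB1 (−1.05 ± 0.07), the cyclin gene CCNB1 (−1.04 ± 0.08) and KIF20A (−0.93 ± 0.07). DNA replication genes had 32 of 39 lower (35 adjusted over the list alone), with RRM2 at −0.93 ± 0.07. Estrogen-induced genes had 29 of 47 lower and 2, CCND1 and NHERF1, higher (31 and 4 adjusted over the list alone), with the carbonic anhydrase gene CA12 at −1.53 ± 0.08. Estrogen-repressed genes had 13 of 20 higher and none lower (14 adjusted over the list alone). Cholesterol synthesis genes had 14 of 22 lower and none higher by either adjustment, with ACAT2 at −0.73 ± 0.09 and STARD4 at −0.83 ± 0.12. Stress genes had 9 of 31 lower and 1, DDIT4, higher (11 and 1 adjusted over the list alone), with SLC7A11 at −1.19 ± 0.12 and ASNS, asparagine synthetase, at −0.67 ± 0.09. Luminal genes had 7 of 23 higher and 2, KRT8 and KRT18, lower (9 and 2 adjusted over the list alone), with MLPH at +0.48 ± 0.08. A pair of further luminal rises were lost without 1 array each, CD24 at +0.28 (adjusted p = 0.052 without ZR75 Y537S Control 3) and GATA3 at +0.28 (adjusted p = 0.063 without ZR75 Y537S Tamoxifen 3). The p53 targets had 4 of 23 higher and 2 lower (8 and 3 adjusted over the list alone), with FUCA1 at +0.73 ± 0.08 and TP53I3 at +0.64 ± 0.12, and the list was lost with the replicate number as a block (adjusted p = 0.061). With an estimated correlation, adjusted p for these 8 lists was 1.6e-06, 0.0006, 6.5e-06, 0.00029, 0.00033, 0.04, 0.046 and 0.046 in the order given. IGF and insulin signalling genes had 4 of 39 higher, IGFBP5, GAB1, TSC1 and RICTOR, and 4 lower, IGF1R, IRS1, GRB14 and EIF4EBP1 (7 and 5 adjusted over the list alone; camera adjusted p = 0.71).

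**Figure D2:**
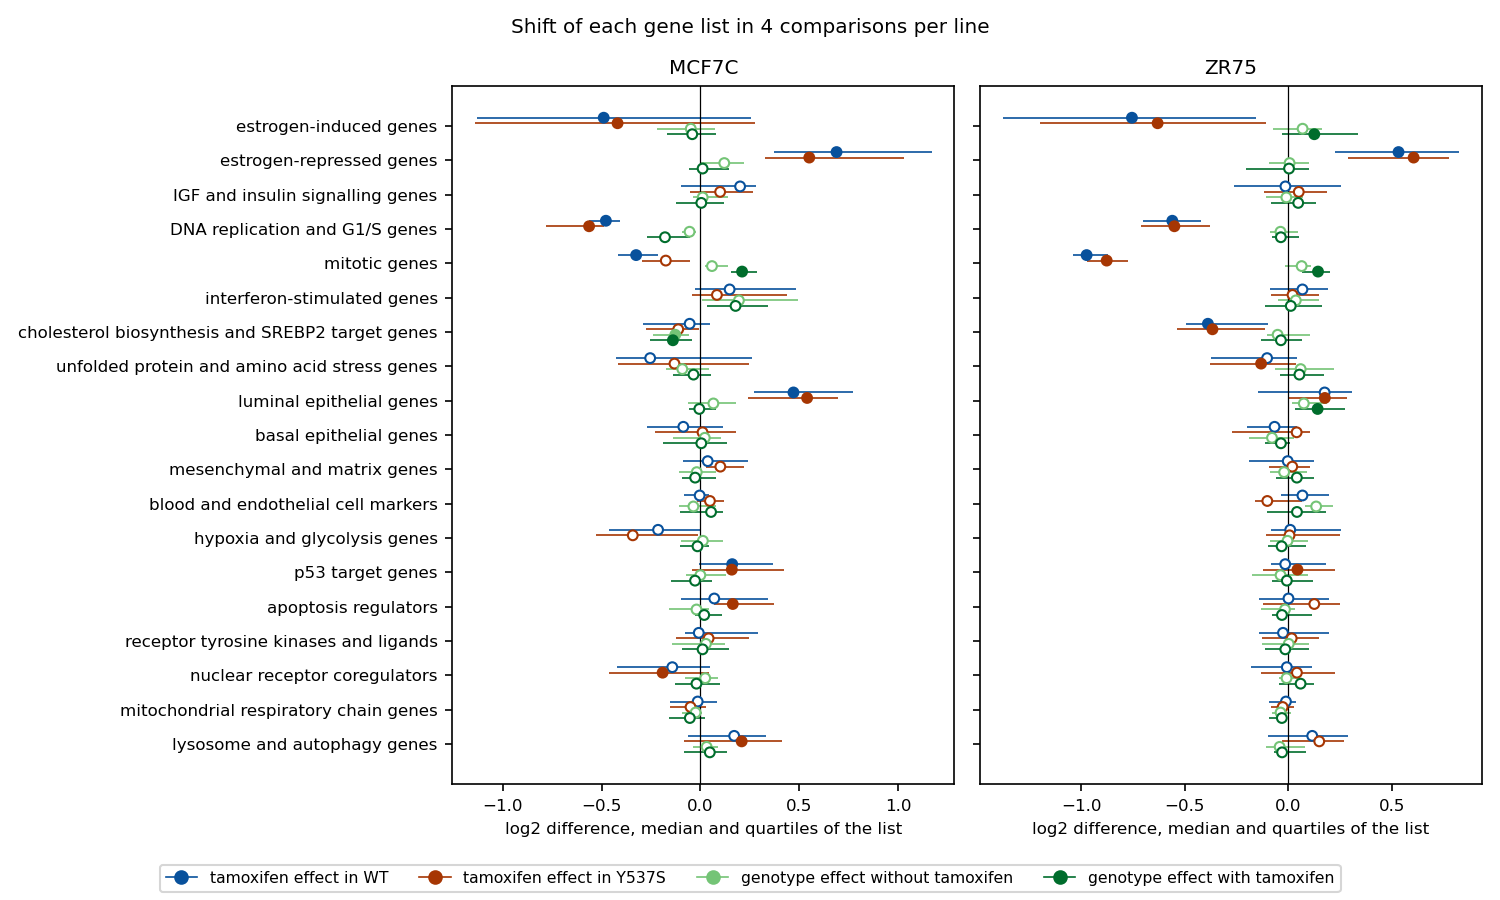
Log2 difference (horizontal axis) of each gene list (vertical axis) in the 4 comparisons of MCF7C (left) and ZR75 (right) cells, with a point at the median of the measured members and a line from the lower to the upper quartile. Filled points mark lists past the threshold with both the preset and an estimated correlation, and the mitotic list in ZR75 cells lies farthest to the left under tamoxifen, with medians of −0.974 and −0.877.

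Many genes answered to tamoxifen in both lines. In WT cells 424 genes were higher and 560 lower in both, against 76.2 and 105 for independent lists, and 55 went opposite ways. In Y537S cells the numbers were 465, 565 and 64, with 82 and 101 for independent lists. LDLRAD4 (+2.25 ± 0.16 in MCF7C and +1.69 ± 0.18 in ZR75 WT cells), DRAIC (+1.58 ± 0.19 and +2.23 ± 0.22) and ACKR3 (+1.53 ± 0.13 and +1.76 ± 0.15) led the shared rises by the smaller change of the lines. PPM1K, the imprinted gene PEG10 (−2.38 ± 0.14 and −1.98 ± 0.16), GREB1, PGR and ELOVL2 (−3.04 ± 0.13 and −1.62 ± 0.14) led the shared falls in WT cells. In Y537S cells the shared rises included IGFBP5 (+1.38 ± 0.11 and +1.39 ± 0.11) and the falls GRB14, an inhibitor of insulin receptor signalling (−1.58 ± 0.17 and −1.39 ± 0.17), and MYBL1 (−1.60 ± 0.10 and −1.45 ± 0.10). With a level under 2 in 1 group, the values of DRAIC and GRB14 in both lines, of LDLRAD4 and ELOVL2 in MCF7C and of ACKR3 in ZR75 cells are lower bounds. Across genes, which are not independent replicates, the differences in the lines correlated with r = 0.402 in WT and 0.405 in Y537S cells.

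The lines also differed, by the test of the difference itself. The tamoxifen effect differed between lines in 1240 genes in WT cells and in 1189 genes in Y537S cells, with 742 and 712 of them higher in MCF7C cells relative to ZR75 cells. With ZR75 WT Control 2 left out, the WT count was 742 in all. Mitotic genes fell more in ZR75 cells, with 34 of 40 members past the difference test in WT cells (39 adjusted over the list alone, median difference +0.653, adjusted p = 8.4e-05 with an estimated correlation). In Y537S cells 36 did (38, median +0.753, adjusted p = 2.8e-05 with an estimated correlation). Luminal genes rose more in MCF7C cells, with 11 of 23 past the difference test in WT cells (13 adjusted over the list alone, adjusted p = 0.00093 with an estimated correlation). The number was 10 in Y537S cells (10 higher and 1 lower adjusted over the list alone, adjusted p = 0.0067 with an estimated correlation). CCN2 and CSTA rose in MCF7C cells and not in ZR75 cells (−0.23 ± 0.21 and −0.18 ± 0.23 in ZR75 WT, near the floor), with differences between the lines of 3.80 and 3.64. NPY1R and EGR3 fell more in ZR75 cells, the MCF7C values being −0.79 ± 0.10 and +0.10 ± 0.12 in WT cells and the differences 3.21 and 3.58.

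The question of the mutation by itself was asked of untreated MCF7C cells, where 62 genes were called, against 4078 for tamoxifen in WT cells. AGR2, a protein disulfide isomerase of the endoplasmic reticulum, was lower in Y537S cells by 1 log2 unit (−1.01 ± 0.09, adjusted p = 3.9e-06). So were PAPSS2, which makes the donor for sulfation (−1.03 ± 0.11, adjusted p = 2.6e-05), and PKIA, an inhibitor of protein kinase A (−1.04 ± 0.13, adjusted p = 0.00034). Further falls were those of ARHGAP36 (−1.12 ± 0.15, adjusted p = 5e-04) and the gap junction gene GJA1 (−1.15 ± 0.13, adjusted p = 9.2e-05; mean 0.44 against 1.6, near the floor). Higher in Y537S cells were WIPF1, a regulator of the actin cytoskeleton (+1.11 ± 0.17, adjusted p = 0.002), the collagen gene COL12A1 (+0.82 ± 0.12, adjusted p = 0.0017) and the secreted protein gene NELL2 (+0.75 ± 0.07, adjusted p = 1.6e-05). These calls held whichever array was left out. Another 13 named genes passed the threshold with all arrays and lost it without at least 1 of the 6. Of these, CSTA (+1.14), CECR2 (+0.92), SELENOP (+0.73), PDZK1 (−1.02), PRSS23 (−0.88), TP53INP1 (+0.52), YPEL3 (+0.61), FHL2 (−0.86), IRF7 (+0.57) and CALB2 (−1.01) were lost without WT Control 1 (adjusted p up to 0.25), without WT Control 3 (up to 0.16) and without Y537S Control 2 (up to 0.23). CAB39L (+0.69), OPTN (+0.85) and ISG20 (−0.51) were lost most clearly without WT Control 1 (0.17), WT Control 2 (0.17) and WT Control 3 (0.1) in that order. CECR2, SELENOP and FHL2 had a level under 2 in 1 group. Some of the 13 were also lost without WT Control 2 (up to 0.17), Y537S Control 1 (up to 0.2) or Y537S Control 3 (up to 0.085). With the mean of a gene's probe sets COL12A1 was at 0.25 (adjusted p = 0.17). PAPSS2 had 1 of its 2 other probe sets called in the same direction. AGR2, PKIA, WIPF1 and COL12A1 had other probe sets too, but none of these was called in either direction.

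Altogether 62 genes passed in untreated MCF7C cells, 33 higher and 29 lower. The count was 21 without WT Control 1, 27 without WT Control 3, 27 without Y537S Control 2 and 112 without Y537S Control 3. In Y537S Control 3 the 3′ minus 5′ signal of GAPDH was 0.589, against 1.08 in Y537S Control 1 and 1.06 in Y537S Control 2. Cholesterol synthesis genes were lower as a group in Y537S cells (median −0.127, adjusted p = 0.027 with an estimated correlation), although none of the 22 passed alone and 4 were lower when adjusted over the list alone. Estrogen-induced genes had PDZK1, PRSS23 and FHL2 lower of 47 (8 lower adjusted over the list alone), and camera's call was lost to adjusted p = 0.28 with an estimated correlation. Estrogen-repressed genes had TP53INP1 and YPEL3 higher of 20 by either adjustment, with adjusted p = 0.22 with an estimated correlation. Interferon-stimulated genes had IRF7 higher and ISG20 lower of 43 (8 and 1 adjusted over the list alone), with adjusted p = 0.22 with an estimated correlation. Replication (median −0.0547) and mitotic genes (median +0.0587) had no member past the threshold by either adjustment, with adjusted p = 0.57 and adjusted p = 0.28 with an estimated correlation. Of the IGF and insulin signalling genes none of 39 passed (2 higher adjusted over the list alone; camera adjusted p = 0.16), with IGF1R at +0.26 ± 0.11, adjusted p = 0.47. A single Y537S derivative stands for each line as far as the labels show, so differences between derivatives and effects of the mutation cannot be separated.

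Under tamoxifen the MCF7C genotypes differed in 89 genes, 32 higher and 57 lower in Y537S cells. Mitotic genes were higher in Y537S cells as a group (median +0.211, adjusted p = 0.0052 with an estimated correlation), with 2 of 40 past the threshold over all genes and 17 higher adjusted over the list alone. The 2 were ASPM, a spindle pole gene (+0.43 ± 0.07, adjusted p = 0.0056), and the spindle assembly gene TPX2 (+0.39 ± 0.08, adjusted p = 0.038). ASPM was at 0.35 (adjusted p = 0.4) with the mean of its probe sets, and lost with each line fitted on its own (0.056) or without WT Tamoxifen 3 (0.053). TPX2 was lost without any of the 6 arrays (adjusted p = 0.062 to 0.19) and with each line fitted on its own (0.13). The median of the mitotic list, relative to each gene's mean over the 23 arrays, was 0.377 to 0.417 in the 3 Y537S arrays and 0.164 to 0.188 in the 3 WT arrays, a separation that chance gives in 10% of comparisons of 3 against 3 arrays. The groups also differed in a sign of RNA quality, since the 3′ minus 5′ signal of GAPDH was 0.537 to 0.606 in the 3 Y537S Tamoxifen arrays and 0.743 to 1.02 in the 3 WT Tamoxifen arrays, while that of actin was 2.54 to 2.86 and 2.64 to 2.98. Cholesterol synthesis genes were lower as a group (median −0.139, adjusted p = 0.017 with an estimated correlation), with MSMO1, a sterol oxidase, past the threshold (−0.51 ± 0.07, adjusted p = 0.00099) and 8 of 22 lower adjusted over the list alone. Replication genes were lower by camera (median −0.179; 12 of 39 adjusted over the list alone), with adjusted p = 0.08 with an estimated correlation. Of them CDC6 alone passed over all genes (−0.69 ± 0.12, adjusted p = 0.0087), and it was lost without WT Tamoxifen 3 (0.087) or Y537S Tamoxifen 1 (0.082). Interferon-stimulated genes had ISG20 lower of 43 (−0.58 ± 0.10, adjusted p = 0.0043, but 0.067 with each line fitted on its own; 2 higher and 1 lower adjusted over the list alone), against a median of +0.178, and adjusted p = 0.27 with an estimated correlation. The respiratory chain list had no member past the threshold (median −0.0533, adjusted p = 0.77 with an estimated correlation), and the IGF list none either (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.88). PGR was lower in Y537S cells (−0.53 ± 0.11, adjusted p = 0.025, near the floor), lost without WT Tamoxifen 2 (0.11), Y537S Tamoxifen 1 (0.15) or Y537S Tamoxifen 2 (0.14). That call was also lost with the replicate number as a block (0.064) and with each line fitted on its own (0.11). IGF1R stood at +0.40 ± 0.11, adjusted p = 0.14, and at +0.52 (adjusted p = 0.042) without WT Tamoxifen 1.

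Among the 89 genes were 5 of at least 2-fold, singled out after their values were seen: SOWAHA (−1.31 ± 0.11, adjusted p = 1.7e-06), PAPSS2 (−1.10 ± 0.11), VMP1 (−1.39 ± 0.27), S100A8 (−1.005, adjusted p = 0.018) and WIPF1 (+1.24 ± 0.17, from a level near the floor). The count fell to 30 without WT Tamoxifen 3, 39 without Y537S Tamoxifen 1, 48 without Y537S Tamoxifen 2 and 49 without Y537S Tamoxifen 3. Of the genes called in both treatments, 10 were higher and 12 lower in Y537S cells each time, against 0.0534 and 0.0836 for independent lists, and none was opposite. AGR2, PAPSS2, PKIA, NELL2, COL12A1 and WIPF1 were among these 22, and each treatment had its own arrays.

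The effect of the mutation without tamoxifen was next asked in ZR75 cells. Higher in Y537S cells were RALYL, an RNA-binding protein gene (+1.48 ± 0.16, adjusted p = 4e-05), SCGB2A2, which encodes mammaglobin A (+1.40 ± 0.18, adjusted p = 3e-04), and the immediate early transcription factor gene EGR1 (+1.34 ± 0.10, adjusted p = 4e-07). The calcium-binding protein gene S100A6 (+1.10 ± 0.13, adjusted p = 8.4e-05) and LONRF2 (+1.09 ± 0.14, adjusted p = 3e-04) were higher too, as was ELF5, a transcription factor gene of the milk-secreting lineage (+1.03 ± 0.11, adjusted p = 3e-05). Lower were BASP1, a membrane-bound signalling protein gene (−1.63 ± 0.20, adjusted p = 0.00013), and the cytokine gene TNFSF15 (−1.56 ± 0.18, adjusted p = 8.4e-05). The values of SCGB2A2, LONRF2, BASP1 and TNFSF15 are lower bounds, with a level under 2 in 1 group. NELL2 was higher, as in MCF7C cells (+0.63 ± 0.08, adjusted p = 3e-04). These calls held whichever array was left out, while the mean of a gene's probe sets gave 0.78 for LONRF2 (adjusted p = 0.11). COL12A1 (+0.83) was not past the threshold without WT Control 2 (adjusted p = 0.18) and PKIA (−0.90) without WT Control 1 (0.15). Losses without WT Control 2 were also seen for PSAT1 (+1.10, 0.25, near the floor), GULP1 (−0.98, 0.082), MPPED2 (−0.96, 0.18), SLCO4C1 (+1.06, 0.32, near the floor), ZNF800 (−1.12, 0.27), CCDC88A (−1.27, 0.11) and RTN1 (−0.85, 0.19). CCDC88A, ZNF800 and RTN1 were lost as well without WT Control 1 (0.13, 0.1 and 0.078) and without Y537S Control 3 (0.07, 0.1 and 0.078). ZNF800 and SLCO4C1 were lost without Y537S Control 1 (each 0.073), and SLCO4C1 without Y537S Control 2 (0.084). The mean of a gene's probe sets gave −0.21 for CCDC88A (adjusted p = 0.4) and −0.41 for ZNF800 (0.097). It gave −0.50 for MPPED2 (0.06) and +0.50 for PSAT1 (0.2).

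In all 60 genes passed in untreated ZR75 cells, 38 higher and 22 lower, and the count was 36 without WT Control 1, 22 without WT Control 2 and 31 without Y537S Control 3. None of the 3 lists that passed held with an estimated correlation. Stress genes had PSAT1 and the asparagine synthetase gene ASNS (+0.54) higher of 31 (3 adjusted over the list alone; adjusted p = 0.28 with an estimated correlation), ASNS being lost without WT Control 1 (0.096) or WT Control 2 (0.14). By the mean of its probe sets ASNS was at +0.32 (adjusted p = 0.15). Luminal genes had none of 23 past the threshold (2 higher adjusted over the list alone, and adjusted p = 0.13 with an estimated correlation). Blood and endothelial markers had CORO1A, an actin regulator of white blood cells, higher of 15 by either adjustment (+0.82), a call lost without any of the 5 arrays (adjusted p = 0.053 to 0.39), and the list had adjusted p = 0.055 with an estimated correlation. For IGF and insulin signalling genes none of 39 passed by either adjustment (camera adjusted p = 0.92), with IGF1R at +0.01 ± 0.13, adjusted p = 0.98 and IRS1 at +0.31 ± 0.11, adjusted p = 0.36.

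With tamoxifen, ZR75 genotypes differed in 103 genes, 69 higher and 34 lower in Y537S cells. Estrogen-induced genes were higher as a group (median +0.126, adjusted p = 0.013 with an estimated correlation), with 5 of 47 past the threshold and none lower (16 and 4 adjusted over the list alone). The 5 were the cytokine gene IL20 (+1.27 ± 0.12, adjusted p = 3.7e-06; near the floor in WT cells), NPY1R (+0.79 ± 0.10, adjusted p = 0.00022), EGR3 (+0.92 ± 0.13, adjusted p = 0.00034; mean 1.54 against 0.62, near the floor), the vesicle transport GTPase gene RAB31 and the anti-apoptotic gene BCL2. RAB31 was at +0.49 ± 0.07, adjusted p = 0.00061 and BCL2 at +0.55 ± 0.10, adjusted p = 0.0079. Luminal genes were higher (median +0.142, adjusted p = 0.013 with an estimated correlation), with KRT8 and CLDN4 past the threshold of 23 and 8 adjusted over the list alone. KRT8 (+0.47) was lost without WT Tamoxifen 1 (0.092), WT Tamoxifen 3 (0.089), Y537S Tamoxifen 1 (0.099) or Y537S Tamoxifen 2 (0.095). CLDN4 (+0.51) was lost without WT Tamoxifen 1 (0.11), Y537S Tamoxifen 2 (0.06) or Y537S Tamoxifen 3 (0.11), and with the mean of its probe sets (0.36). Mitotic genes were higher too (median +0.144, adjusted p = 0.028 with an estimated correlation), none of 40 past the threshold alone and 7 adjusted over the list alone. Stress genes had PSAT1 higher of 31 (+0.95 ± 0.17, adjusted p = 0.0053, near the floor; 5 higher and 1 lower adjusted over the list alone), with adjusted p = 0.31 with an estimated correlation. PSAT1 was at 0.40 (adjusted p = 0.26) with the mean of its probe sets, and its adjusted p was 0.051 with each line fitted on its own. IGF and insulin signalling genes had none of 39 past the threshold (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.53). IGF1R was at +0.38 ± 0.11, adjusted p = 0.18, the same direction as in MCF7C cells. Trend and robust moderation called it in both lines (adjusted p = 0.035 in ZR75 and 0.02 in MCF7C). In ZR75 cells the 3′ minus 5′ signal of GAPDH was 0.727 to 0.845 in the Y537S Tamoxifen arrays and 0.643 to 0.713 in the WT Tamoxifen arrays. That of actin went the other way, with 2.01 to 2.31 and 2.19 to 2.4.

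Of the ZR75 genotype differences, 19 genes were higher and 13 lower with and without tamoxifen, against 0.133 and 0.0378 for independent lists, and none was opposite. RALYL, SCGB2A2, EGR1, S100A6 and ELF5 were among the higher and BASP1 (−1.70 ± 0.18 with tamoxifen) and TNFSF15 (−1.93 ± 0.16, near the floor in Y537S cells) among the lower. Between the lines little was shared. Without tamoxifen COL12A1 and NELL2 were higher and PKIA lower in Y537S cells of both lines, against 0.0634 and 0.0323 genes for independent lists. A further 2 genes, singled out after their values were seen, went opposite ways, the stem cell factor gene KITLG (+0.66 ± 0.09 in MCF7C and −0.83 ± 0.10 in ZR75) and the synaptotagmin gene SYT1 (+0.46 ± 0.07 and −0.73 ± 0.08). With tamoxifen NELL2 and SLC7A2 were higher and PKIA and GULP1 lower in both, against 0.112 and 0.098. Another 6 genes went opposite ways, ELF5, ITPRID2, KITLG, SCD, SYT1 and TXNIP, likewise singled out afterwards. Correlations of the genotype differences between lines across genes, which are not independent replicates, were r = 0.0591 without and 0.0996 with tamoxifen. By the test of the difference itself, the genotype effect without tamoxifen differed between lines in 47 genes, a count of 29 without MCF7C WT Control 3, 31 without MCF7C Y537S Control 2 and 21 without ZR75 WT Control 2.

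Whether the mutation altered the response to tamoxifen was tested by the interaction. In MCF7C cells limma called 0 genes, with 1351 at an unadjusted p under 0.05. The smallest adjusted p belonged to TAL1 (+0.80 ± 0.13, adjusted p = 0.074), WDR90 (−0.99 ± 0.17, adjusted p = 0.074), GJA1 (+1.07 ± 0.19, adjusted p = 0.082) and TMEM169 (+1.06 ± 0.20, adjusted p = 0.13), none past the threshold. Trend and robust moderation called 6 genes, and the other 8 settings run on all genes called 0. Leaving out WT Tamoxifen 1 gave 7 genes, including WDR90 (adjusted p = 0.0074) and TAL1 (0.028). Leaving out WT Control 2 gave 2, including GJA1 (0.0055), and leaving out Y537S Control 2 or Y537S Control 3 gave 1 each, in the first case TAL1 (0.039). ZR75 cells likewise had 0 genes, with 1118 at an unadjusted p under 0.05 and 0 in all other settings except 3 without Y537S Control 2. The genes with the smallest p there were TNFSF13 (−0.77 ± 0.13, adjusted p = 0.15), WDFY3-AS2 (+0.99 ± 0.19), KRTAP8-1 (+0.67 ± 0.13) and RASD1 (−1.05 ± 0.21).

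No single estrogen response or IGF pathway gene had an interaction past the threshold over all genes. GREB1 had +0.51 ± 0.28, adjusted p = 0.78 in MCF7C and +0.55 ± 0.30, adjusted p = 0.92 in ZR75 cells. PGR had −0.21 ± 0.15, adjusted p = 0.84 and +0.12 ± 0.16, adjusted p = 0.98, and ESR1 −0.18 ± 0.11 and +0.12 ± 0.11. IGF1R had +0.14 ± 0.16, adjusted p = 0.92 and +0.37 ± 0.17, adjusted p = 0.86, and IRS1 +0.03 ± 0.14 and +0.05 ± 0.15. IGF and insulin signalling genes did not shift as a list, with medians of −0.0372 (camera adjusted p = 0.58) in MCF7C and +0.0506 (0.59) in ZR75 cells, and none of 39 passed by either adjustment. Mitotic genes had a positive interaction by camera in both lines, meaning a smaller fall with tamoxifen in Y537S cells (medians +0.128 and +0.0865), with adjusted p = 0.44 and adjusted p = 0.68 with an estimated correlation. Replication genes had a negative one in MCF7C cells (median −0.122, adjusted p = 0.45 with an estimated correlation), and estrogen-induced genes a positive one in ZR75 cells (median +0.0962, 2 higher adjusted over the list alone, adjusted p = 0.55 with an estimated correlation). The estrogen-repressed list did not pass in MCF7C cells (median −0.124, camera adjusted p = 0.11), but did without MCF7C Y537S Control 1 and ZR75 Y537S Tamoxifen 2, whose control probe sets stood apart (0.044). On simulated data 88.1% of genes with a true interaction of 1 log2 unit and 17.9% of those with 0.5 were called in MCF7C cells. The shares were 71.6% and 29.9% in ZR75 cells, so interactions of about 0.5 were mostly not called there. Each share rests on 1 draw with 67 changed genes, whose changes were not made smaller near the floor. The plot of the tamoxifen effect in Y537S against WT cells shows the values behind these tests.

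**Figure D3:**
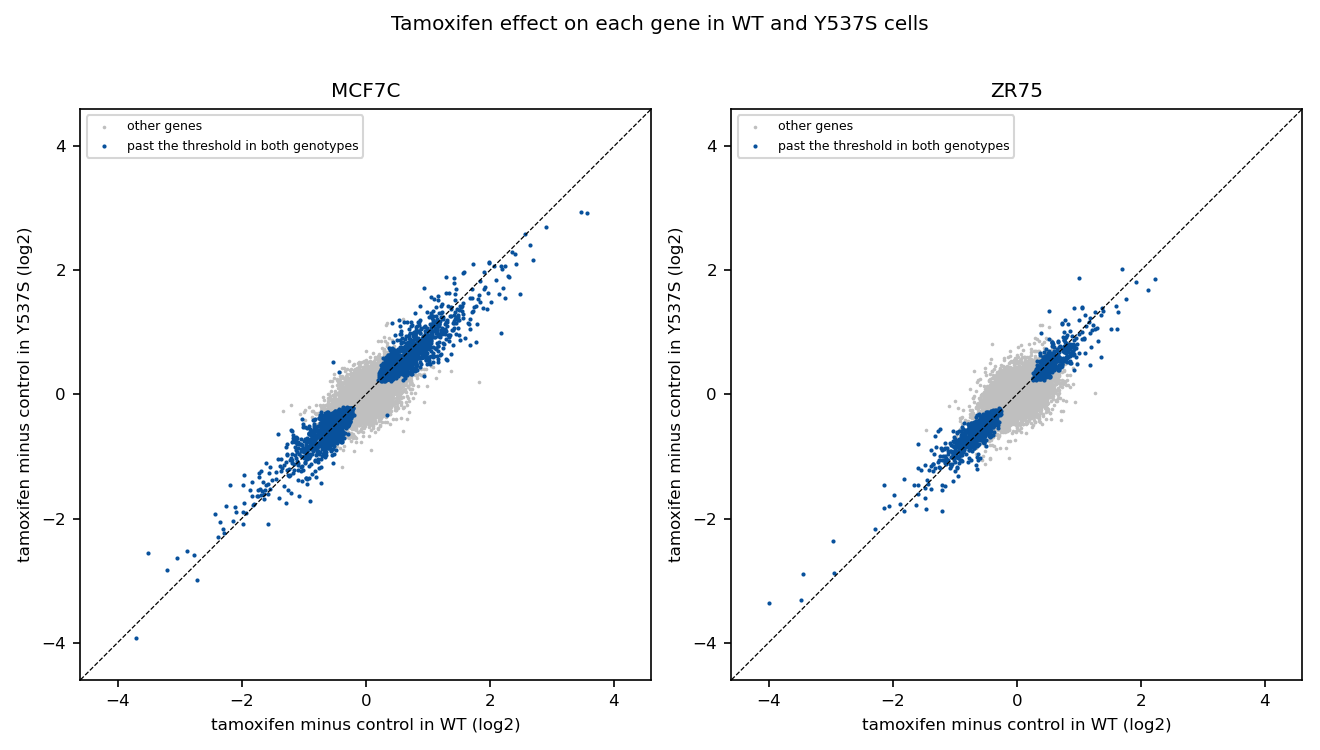
Tamoxifen minus Control in Y537S cells (vertical axis, log2) against the same difference in WT cells (horizontal axis, log2) for MCF7C (left) and ZR75 (right) cells, with 1 point per gene, blue where past the threshold in both genotypes, and a dashed line at equality. The points follow the line, with r = 0.811 in MCF7C and 0.682 in ZR75 cells across genes.

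The size of the response was also measured with genes chosen by their change in the other line. The spread behind those calls and the choice of probe set came from all 23 arrays. In MCF7C cells the 1181 genes called in both genotypes of ZR75 cells moved by a mean of 0.447 in WT and 0.425 in Y537S cells in the ZR75 direction, with an interaction of −0.0227. In ZR75 cells the 2706 genes chosen in MCF7C cells moved by 0.259 and 0.242, with an interaction of −0.0177. Neither interaction passed in the rotation test fry (unadjusted values of 0.38 and 0.48). Without tamoxifen the same 1181 genes lay 0.0688 toward the tamoxifen state in MCF7C Y537S relative to WT cells, and with tamoxifen 0.0461. Fry gave unadjusted values of 0.0011 and 0.015 for these shifts. The ZR75 shifts were 0.0241 and 0.00634, with 0.2 and 0.67 in fry. The basal epithelial list and that of receptor tyrosine kinases and their ligands did not pass camera with the preset correlation in any of the 10 comparisons within lines, and their medians and means differed in sign in some of them. With fry the receptor tyrosine kinase list passed for tamoxifen in MCF7C WT (adjusted p = 3.8e-06) and Y537S cells (2e-05). The basal list passed with fry for tamoxifen in ZR75 WT (adjusted p = 0.024) and Y537S cells (0.049), and with the replicate block in the former (0.042).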

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

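The results below were picked out by the test of the difference between lines, chosen in advance. Of the tests weighed for the 3 patterns at the end, the effect of 1 array on the shift of untreated MCF7C Y537S cells and the counts over other splits were set before their results were seen, and the rest were chosen after.

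Values in brackets are the MCF7C effect minus the ZR75 effect, in log2, for named genes past the threshold of that test. Where the effect in a line was given above as near the floor or as a lower bound, its difference between lines is only approximate. HMGCLL1, PRSS23 and PGR in Y537S cells are examples. For the genotype effect without tamoxifen, 17 genes differed, with SE of 0.13 to 0.27 and adjusted p up to 0.038. Relatively higher in MCF7C Y537S cells were TNFSF15 (+1.78) and WIPF1 (+1.22). Relatively higher in ZR75 Y537S cells were RALYL (−1.62), SCGB2A2 (−1.58), PSAT1 (−1.44), SLCO4C1 (−1.44), LONRF2 (−1.33), GJA1 (−1.25), ARHGAP36 (−1.20), S100A6 (−1.20), CORO1A (−1.18), EGR1 (−1.17), ELF5 (−1.15), AGR2 (−0.91), C3orf70 (−0.88), ISG20 (−0.73) and ASNS (−0.63).

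For the tamoxifen effect in WT cells, 49 named genes differed, with SE of 0.10 to 0.32 and adjusted p up to 0.041. Less decrease or more increase in MCF7C than in ZR75 cells was found for CCN2 (+3.80), CSTA (+3.64), EGR3 (+3.58), NPY1R (+3.21), CYP2B7P (+3.04), LINC01588 (+2.92), TCN1 (+2.91), SOCS3 (+2.42), IER3 (+2.14), GREB1 (+1.47), YPEL3 (+1.40), PPFIBP2 (+1.39), CDKN1A (+1.33), PARP9 (+1.13), SLC2A1 (+0.96), CTSD (+0.96), IFITM2 (+0.88), GDF15 (+0.86), CD24 (+0.85), ESR1 (+0.84), PLK2 (+0.81), SPDEF (+0.76), ELF3 (+0.74), BUB1 (+0.72), CEP55 (+0.72), BUB1B (+0.65), WIPI1 (+0.64), RRM2 (+0.64), TFF1 (+0.61), TP53INP1 (+0.61), IGFBP5 (+0.56), CDC20 (+0.54), GINS1 (+0.40) and MSMO1 (+0.38). The opposite was found for PRSS23 (−2.87), THBS1 (−2.71), PDZK1 (−2.27), PGR (−1.83), CMAHP (−1.66), ELOVL2 (−1.42), ATP8A1 (−1.18), IL20 (−1.09), HERC5 (−1.02), BNIP3 (−0.82), NPNT (−0.70), LDHA (−0.59), DDIT4 (−0.58), KDM1A (−0.50) and P4HA1 (−0.48).

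For the tamoxifen effect in Y537S cells, 49 named genes differed, with SE of 0.10 to 0.30 and adjusted p up to 0.044. Values were higher in MCF7C cells for EGR3 (+3.45), CSTA (+2.91), LINC01588 (+2.69), CCN2 (+2.65), NPY1R (+2.57), SOCS3 (+2.53), TCN1 (+2.53), CYP2B7P (+2.36), TM4SF1 (+2.18), CA12 (+1.94), IER3 (+1.79), GREB1 (+1.44), CCN1 (+1.24), CDKN1A (+1.18), YPEL3 (+1.00), CD24 (+0.89), SLC2A1 (+0.87), KIF20A (+0.86), CCNB1 (+0.82), CLDN4 (+0.77), BUB1 (+0.74), ELF3 (+0.69), PLK2 (+0.67), AGR2 (+0.63), AURKB (+0.60), KIF2C (+0.58), ESR1 (+0.54), BUB1B (+0.48), SQLE (+0.46), RRM2 (+0.45), GDF15 (+0.44), CDC20 (+0.42) and TYMS (+0.38). They were higher in ZR75 cells for HMGCLL1 (−3.22), PRSS23 (−2.70), PGR (−2.16), PDK1 (−1.76), CEACAM6 (−1.55), IL20 (−1.47), PDZK1 (−1.36), BNIP3 (−0.98), ELOVL2 (−0.85), TP53I3 (−0.82), ATP8A1 (−0.79), IGFBP4 (−0.67), LDHA (−0.61), RERG (−0.59), NPNT (−0.50) and DDIT4 (−0.44). One gene, DCLK1, singled out after its values were seen, differed between lines in the interaction (−1.30 ± 0.19, adjusted p = 0.029), with −0.70 in MCF7C and +0.60 in ZR75 cells. The interaction of DCLK1 was past the threshold in neither line alone, and its call was lost without 17 of the arrays.

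Other splits of the arrays were counted for the comparisons with 3 arrays in each group. The 10 splits of 6 arrays are too few for a share under 0.05. The real split called 62 genes for the MCF7C genotype effect without tamoxifen (highest of the others 1), 89 with tamoxifen (0), 4078 for tamoxifen in WT (0) and 3585 in Y537S cells (0). In ZR75 cells it called 103 for the genotype effect with tamoxifen (0) and 2012 for tamoxifen in Y537S (0), so that in each of them 1 split, the real one, gave as many. For the MCF7C interaction all 100 drawn splits gave at least the real count of 0, which any split must, so that count decides nothing. The highest of the others, 308, came from exchanging the genotype labels in one treatment, which adds the genotype effects in place of subtracting them, and the next highest was 8. For the difference between lines in the tamoxifen effect in Y537S, 5 of 100 splits gave at least the 1189 genes of the real one, the real one included, which is not under 0.05. The highest, 4200, came from exchanging the treatment labels in one line, which adds the effects of the lines. Splits that exchange most labels in one line carry such added effects too, so these splits are no measure of chance and the count decides nothing.

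Mitotic genes were higher in Y537S than in WT cells under tamoxifen in both lines. Without tamoxifen the list also lay higher in Y537S arrays, by its median relative to each gene's mean. That median was 0.52 to 0.557 against 0.459 to 0.503 in MCF7C cells and 0.0919 to 0.141 against 0.0223 to 0.0302 in ZR75 cells. The interaction of this list held in neither line with an estimated correlation, so the difference cannot be called particular to tamoxifen. A larger share of cycling cells predicts a rise of the replication and G1/S list as well, which was not seen in MCF7C cells. That list was lower in Y537S cells (median −0.179, fry adjusted p = 0.0037, camera adjusted p = 0.08 with an estimated correlation). Fry does not compare it with other genes, and camera with that correlation did not pass, so the share of cycling cells stays open there. In ZR75 cells the median of that list was −0.0355, which decides nothing. Less degraded RNA in Y537S cells stays open in both lines and cannot be told apart from genotype, since the 3′ minus 5′ signal was lower in MCF7C cells for GAPDH (−0.36) and actin (−0.16, within the SD of 0.17), and in ZR75 cells higher for GAPDH (+0.12) and lower for actin (−0.19). No biological explanation other than the share of cycling cells was tested.

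Untreated MCF7C Y537S cells lay 0.0688 toward the tamoxifen state on the genes chosen in ZR75 cells. A single array as the source is argued against, as the shift was at least 0.0553 whichever of the 6 arrays was left out. Tamoxifen-treated material in the untreated Y537S samples needs equal shares from rising and falling genes, and the falling genes gave a share higher by 7.67 percentage points over 9 pairs of arrays (SD 6.31). That test, whose criterion was revised after a first result, cannot separate such material from a change in the cells. Lower estrogen receptor output may account for the shift, but the estrogen-induced list had adjusted p = 0.28 with an estimated correlation, so it stays open as does any other difference between the derivatives.

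In ZR75 cells under tamoxifen, 6 of the 9 ESR1 probe sets were lower in Y537S than in WT cells, and 2 of these passed the threshold (−1.27 ± 0.17, adjusted p = 0.00028, and −0.62 ± 0.13, adjusted p = 0.043), although the brightest was not lower. The smallest of the 6 differences was −0.03 ± 0.14, near the floor. Without tamoxifen the same 2 were lower in ZR75 Y537S cells as well (−0.81 ± 0.18 and −0.63 ± 0.15), not past the threshold, with the brightest at +0.16 ± 0.09. In MCF7C cells these 2 were at −0.36 ± 0.17 and −0.10 ± 0.13 without tamoxifen. With it they were at −0.13 ± 0.17 and −0.16 ± 0.13, none past the threshold. Lower ESR1 as a whole stays open. The brightest probe set, at +0.28 ± 0.08, passed only with trend and robust moderation (adjusted p = 0.009). The mean of the 9 was called lower (−0.35 ± 0.07). A lower signal of all probe sets as dim as the most changed one is argued against by their median of 0.0049. Transcripts that differ along the gene stay open, as the annotation used here gives no positions of the probe sets.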

How the results depend on the processing

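The alternative without MCF7C Y537S Control 1 and ZR75 Y537S Tamoxifen 2, whose control probe sets stand apart, was chosen after seeing the data, and the other alternatives before.

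Signal over background limits these results, since 8544 of 19775 genes had a mean of at least 3 and changes near the floor are understated. Array number limits them too, and a ZR75 WT Control group left with a single array is assumed to vary like the other groups. Both scaling alternatives moved the median of all genes by at most 0.022. Replicate numbers did not pair the arrays: residuals of arrays with the same number correlated with medians of 0.019 in MCF7C and 0.023 in ZR75 cells across genes, which are not independent replicates, and 5 of 12 and 4 of 11 arrays correlated best with an array of their own number. With that number as a block, the genotype effect differed between lines in 27 genes in place of 47.

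Counts of called genes moved by over 1.5 times as follows, and except where fewer genes, fewer arrays or a stricter minimum account for it, the cause was not tested. Each line fitted on its own, which leaves fewer arrays for the spread, gave 23 genes for the MCF7C genotype effect without tamoxifen and 37 with it, and 30 and 63 in ZR75 cells. Trend and robust moderation gave 135 and 272 in MCF7C and 98 and 206 in ZR75 cells, 6 for the MCF7C interaction and 71 for the difference between lines in the genotype effect. Array weights gave 179 for MCF7C with tamoxifen. Without the genes of lowest mean, 158 were called there and 93 in untreated ZR75 cells, and 10 genotype differences with tamoxifen were shared between lines in place of 4. The 1 gene called for the difference between lines in the interaction, DCLK1, fell to 0 with trend and robust moderation, the mean of probe sets, the replicate block and without the arrays that stand apart. With a minimum of 1 log2 unit, the genotype effects kept 10 and 5 genes in MCF7C and 12 and 14 in ZR75 cells. The tamoxifen effects kept 368 in WT and 307 in Y537S MCF7C cells and 133 and 119 in ZR75 cells. Differences between lines kept 23, 279 and 226 for genotype, tamoxifen in WT and tamoxifen in Y537S, and 0, 0, 34 and 33 genes were shared between lines for genotype without and with tamoxifen and for tamoxifen in WT and Y537S.

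Lists past the threshold with an estimated correlation numbered 1, 2 and 6 of 19 for the MCF7C genotype effects without and with tamoxifen and tamoxifen in WT, 0 for the MCF7C interaction, and 0 in ZR75 cells for genotype without tamoxifen and for the interaction. Fry gave 1 and 3 for the MCF7C genotype effects and 0 for both interactions, and without the arrays that stand apart the MCF7C interaction had 4 lists, with the estrogen-repressed (adjusted p = 0.044) and respiratory chain genes (0.005) added. Of 190 list results, an estimated correlation ended 26, fry ended 12 and added 15, and the block ended 1, the p53 target genes for tamoxifen in ZR75 Y537S cells (adjusted p = 0.061). It added 2, the interferon-stimulated genes for tamoxifen in MCF7C Y537S cells (adjusted p = 0.036) and the basal genes for tamoxifen in ZR75 WT cells (adjusted p = 0.042).

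Leaving out 1 array gave 21 to 112 genes for the MCF7C genotype effect without tamoxifen and 30 to 100 with it, 3303 to 3648 for tamoxifen in WT, 2893 to 3337 in Y537S and 0 to 7 for the interaction. In ZR75 cells the ranges were 22 to 67, 69 to 90, 940 to 1510, 1479 to 1686 and 0 to 3. Differences between lines ranged from 21 to 46 for genotype, 742 to 1149 for tamoxifen in WT, 948 to 1160 in Y537S and 0 to 2 for the interaction. For MCF7C without tamoxifen the count was 21 without WT Control 1, 27 without WT Control 3, 27 without Y537S Control 2 and 112 without Y537S Control 3. With tamoxifen it was 30 without WT Tamoxifen 3, 39 without Y537S Tamoxifen 1, 48 without Y537S Tamoxifen 2 and 49 without Y537S Tamoxifen 3. The MCF7C interaction had 7 genes without WT Tamoxifen 1, 2 without WT Control 2 and 1 without Y537S Control 2 or Y537S Control 3. In ZR75 cells the count was 36 without WT Control 1, 22 without WT Control 2 and 31 without Y537S Control 3 for genotype without tamoxifen, 1049 and 940 without WT Control 1 and 2 for tamoxifen in WT, and 3 for the interaction without Y537S Control 2. Between lines it was 29 without MCF7C WT Control 3, 31 without MCF7C Y537S Control 2 and 21 without ZR75 WT Control 2 for genotype, and 742 without ZR75 WT Control 2 for tamoxifen in WT. DCLK1's comparison had 1 gene without MCF7C WT Control 2, WT Tamoxifen 3, Y537S Control 1 or Y537S Tamoxifen 3, 0 without each of 17 other arrays and 2 without MCF7C Y537S Tamoxifen 2 or ZR75 Y537S Control 2.

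Of 286 calls of named genes, 22 ended with each line fitted on its own, 7 with array weights, 2 with centring, 26 with the mean of probe sets, 9 with the block and 10 of 150 without the arrays that stand apart. Trend and robust moderation, quantile normalization and the filter on dim genes ended none of those they covered. Leaving out 1 array ended 103 of 1652 calls. Of 182 calls of named genes that had other probe sets, 98 had another one called in the same direction and 0 in the opposite one. Of 54 values not past the threshold, 8 passed with trend and robust moderation, among them IGF1R in both genotype effects with tamoxifen, as given above. IGF1R under tamoxifen in MCF7C Y537S cells, with an adjusted p of 0.06, passed under 6 other settings, with adjusted p from 0.001 with the mean of probe sets to 0.049 with centring, and without Y537S Control 3 (0.031). PGR passed with the mean of probe sets in the genotype effects given above. A single value turned its direction, ESR1 in ZR75 cells with tamoxifen, at −0.35 ± 0.07 (adjusted p = 0.016) with the mean of probe sets against +0.28. The cause was not tested beyond its probe set values.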

Other observations

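The genes in this part were chosen only after their values were seen, while the comparisons themselves were set in advance.

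Genes outside the fixed lists were among the genotype differences that held in both treatments. In MCF7C Y537S cells EHF was lower each time (−0.83 ± 0.10 without and −0.87 ± 0.10 with tamoxifen). S100P was too (−0.69 ± 0.11 and −0.79 ± 0.11). So were MARCKS (−0.64 ± 0.09 and −0.75 ± 0.09) and SOWAHA (−0.56 ± 0.11 and −1.31 ± 0.11). RETREG1 was higher (+0.66 ± 0.11 and +0.62 ± 0.11). In ZR75 cells the sodium channel subunit gene SCNN1A (+0.90 ± 0.13 and +0.96 ± 0.12), the calmodulin-like gene CALML5 (+0.88 ± 0.17 and +0.84 ± 0.15), ASS1, an enzyme of arginine synthesis (+0.81 ± 0.08 and +0.75 ± 0.07), and the transcription factor gene JUN (+0.60 ± 0.11 and +0.71 ± 0.10) were higher. The interleukin 1 receptor gene IL1R1 (−0.85 ± 0.15 and −0.86 ± 0.13), the estrogen-metabolizing enzyme gene CYP1B1 (−0.56 ± 0.11 and −0.65 ± 0.10) and ID3 (−0.48 ± 0.10 and −0.64 ± 0.09) were lower. Without tamoxifen S100P in MCF7C Y537S and SCNN1A in ZR75 WT cells were near the floor.

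Under tamoxifen ZR75 genotypes differed by at least 2-fold in 14 genes. Among them, PTGES, which makes prostaglandin E2 (+1.16 ± 0.14, adjusted p = 8e-05), the dystrophin gene DMD (+1.14 ± 0.17, adjusted p = 0.0007), CEACAM6 (+1.12 ± 0.18, adjusted p = 0.0018) and the lysophosphatidic acid receptor gene LPAR3 (+1.08 ± 0.23, adjusted p = 0.029) were higher in Y537S cells, PTGES and LPAR3 from levels near the floor. TXNIP rose with tamoxifen in WT cells of both lines. It was at +1.13 ± 0.09, adjusted p = 2.8e-09 in MCF7C and +1.23 ± 0.10, adjusted p = 2e-08 in ZR75. Under tamoxifen it was higher in MCF7C Y537S than in WT cells (+0.51 ± 0.09) and lower in ZR75 Y537S cells (−0.41 ± 0.09).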
